A study of Homo sapiens with 101 samples.

How the data were processed

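RNA was measured in 101 samples. Per the labels' protocols, total RNA was depleted of ribosomal RNA with Ribo-Zero Gold, and directional libraries were made with a KAPA stranded kit. Of these, 9 are purified cell types and 92 belong to islet time courses. All choices of comparisons, tests, gene lists and settings to vary were made before the data were examined, except where a choice is said to follow from the data.

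For the 9 cell types, the deposited files hold counts of reads per gene. Per the submitters' processing notes they come from alignment to hg19 with TopHat2, SAMtools and HTSeq on GENCODE v19, with no versions stated. Their symbols are those of GENCODE v29, or of the gene symbol column of a deposited table of CPM where the ID is not in v29. The other values of that table were not used, since CPM were computed from the counts. No coordinates are given. For the time courses, the deposited tables hold normalized values (signal), 86 columns and 35390 genes, per the submitters' processing notes from alignment to hg38 with STAR, gene counts from RSEM and normalization with DESeq2. The smallest nonzero value of a column was taken as 1 read. The lowest share, over columns, of nonzero values that are whole multiples of it within 0.01 was 99.997%, so whole read counts were recovered. Size factors computed over both tables jointly matched these steps within a spread of 0.848%, and over each table separately within 1.65% and 7.62%, so both tables are on 1 scale. The deposited files per library hold expected counts from RSEM. Their totals run from 57 to 7762698, 60 of 92 hold under 100000, and 3 equal a table column (at least 99.9% of genes within 0.6), so most hold parts of libraries. They were used for the mock primary islets of CT16 alone.

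The entrained table lists 4 blocks of columns, the primary islets first and the SC series as blocks 2 to 4. The mock table lists SC blocks 1 to 3. The sample titles number the series 1 to 3 in both arms, while columns are named by time without these numbers, so blocks stand for series. Of the SC per-library files, 1 of replicate 1 (CT60) equals a column of entrained block 2 and 1 of replicate 3 (CT16) equals a column of block 4. No mock file equals a column, and blocks were not assigned to replicates by values or order. The entrained primary library of CT52 and the mock primary libraries have no column. Of the table's gene IDs, 35194 were found in GENCODE v29, which gave symbols and the GC content of transcripts as the mean over a gene's transcripts. In all, 64 genes of the Y chromosome and of X inactivation were left out. Library pools were read from the names of the files.

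The design had assumed edgeR on expected counts. Since most of those files hold parts of libraries, the test for each replicated comparison was limma-trend (limma 3.58.1, R 4.3.3) on log2 of the normalized value plus 5, for genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. EdgeR 4.0.16 and DESeq2 1.42.0 ran on the recovered reads as alternatives. Rhythm was tested as a cosine and a sine of 24 h (2 degrees of freedom). The further terms were series by day for the entrained SC islets and for primary against SC islets, series over CT0 to CT20, and day for primary islets. The swing is the fitted distance from trough to peak, and the peak is given in hours of the labelled time. A difference in rhythm is the interaction of those terms with the arm or with primary against SC islets. Its size is the swing of that interaction, which a difference in phase alone can also raise. Entrained and mock SC islets, and day 3 and day 1, were compared on the mean of 6 times per series, 3 against 3. SC and primary islets were to be compared in mock libraries. Since these lack primary columns, entrained libraries at the 14 shared times were used, with no test: the log2 ratio of mean normalized values with 5 added, per SC series, counted by size where the 3 series have the same sign. Other pairs without replicates were compared by the log2 ratio of CPM with 1 CPM added, with no test, and counted as different by size at a log2 ratio of at least 2 with at least 20 CPM in the higher library. Of 34 gene lists fixed before the data were examined, 31 had enough genes for camera at a preset correlation of 0.01, camera at an estimated correlation and fry. Lists among rhythmic genes were tested with a one-sided Fisher's exact test. In unreplicated pairs the median of a list was placed among 10000 random lists matched on mean expression, over genes with at least 1 CPM in the higher library.

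The GC correction subtracts from each library, in each of 20 bins of genes by GC content, the median deviation from the genes' means. The other form of correction uses as a term of the model the correlation, across genes, of GC content with the library's deviation. Both were chosen after seeing the data, as were limma on normalized values with its added constant and filter, TMM scaling of them, edgeR with TMM on recovered reads, the fits of 36 libraries with the series as a random effect, the pool group as a term, and the fits without shallow libraries or those of the other GC sign. Alternatives tried were other added constants, other scalings (TMM, RLE), no filter, other tests, a further term for the pool or the block, and each series left out in turn.

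Named genes are protein-coding per GENCODE v29 and followed a rule. For comparisons of 2 replicated groups they were to be the 10 largest rises and 10 largest falls past the test with the same sign in all pairs and at least 5 CPM. For pairs without replicates, they were the 5 largest ratios each way with at least 20 CPM in the higher library. For rhythms they were the core clock genes and the 15 of smallest p with at least 5 CPM whose own peak in each series lay within 4 h, and for differences in rhythm the 10 of smallest p. For lists, they were up to 4 members past the test, else up to 2 with the largest change. INS, GCG, SST, MAFA, UCN3 and IAPP were named everywhere. A few genes that the rule gives are not reported here. In the comparisons of arms and of days no gene passed, so the 12 genes of smallest p were named there, chosen after values were seen, as were the genes of the fit with the column block as a term and a few genes named beside a list.

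Each test was run on simulated counts with 200 genes changed by 1 log2 at a dispersion of 0.05. It recovered 97.5% of them for the rhythm in entrained SC islets (15883 genes), 37.0% over CT0 to CT20 (15896 genes), 46.0% in mock SC islets (15922 genes), 18.0% in primary islets (15870 genes), 2.00% for the difference in rhythm between arms (15909 genes), 12.0% for that between primary and SC islets (16256 genes), 97.0% for entrained against mock (15906 genes) and 98.5% for day 3 against day 1 (15886 genes). The simulated libraries were drawn independently, without differences between series or in the dependence on GC content. These shares can therefore overstate recovery in the real series. The immediate early list, raised by 0.5 log2, passed camera in both comparisons of 2 groups, where 1 and 2 lists of 31 passed in all. Changes of 3 log2 were recovered for 100% of 200 genes in a cell type pair with counting error alone (8367 genes) and in SC against primary islets (8199 genes). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.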

Results

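RNA was sequenced from 101 human samples in 2 sets. The first set holds 9 libraries of purified live cells, 1 library per cell type, so these comparisons have no replicates. Of these, 7 follow the directed differentiation of HUES 8, a human embryonic stem cell line: pluripotent cells (hPSC), definitive endoderm (DE), pancreatic progenitors 1 and 2 (PP1, PP2), endocrine progenitors (EN), stem-cell-derived beta cells (SCbeta) and poly-hormonal cells (PH). The other two are alpha and beta cells (Alpha, Beta) of adult islets. The second set holds 92 libraries of whole islets, labelled either entrained to circadian metabolic rhythms or mock-treated. SC islets, which were differentiated from HUES 8, have 54 entrained libraries in 3 series (CT0 to CT68) and 18 mock libraries in 3 series (CT0 to CT20). Primary adult islets have 1 entrained series of 15 libraries and 1 mock series of 5. Libraries were taken every 4 h, but the primary islets have none at CT20, CT44 or CT68. Their entrained series runs from CT0 to CT64 and their mock series from CT0 to CT16. The labels name no entrainment agent.

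The cell type libraries hold 31748086 (Alpha) to 91460395 (hPSC) reads assigned to genes. Ambiguous reads made up 1.03% in EN, 0.871% in PH and 1.12% in Alpha, and 2.16% (PP2) to 3.30% (hPSC) in the other cell types. The comparisons of EN with PP2, SCbeta with EN, SCbeta with PH and Alpha with Beta cross this difference. Library quality is not separated from cell type in them. In the deposited time course tables, the entrained SC libraries hold 413504 to 24090155 reads (median 7587634), the mock SC libraries 702614 to 11489184 (median 6583968) and 14 entrained primary libraries 966854 to 58447721 (median 3979572.5). The entrained primary library of CT52 and all 5 mock primary libraries are absent from those tables. Per-library files exist for all 92, but most hold only part of a library, so of the mock primary islets only CT16 had depth for a comparison.

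Between hPSC and DE, genes of anterior and definitive endoderm were higher in DE. CER1, a secreted Nodal and BMP antagonist, stood at a log2 ratio of 9.86, and FGF17 at 9.496. EOMES, a transcription factor of endoderm specification, stood at 8.40 and LHX1 at 8.19. All 11 members of the definitive endoderm list were higher by size, with a median of 7.20. The pluripotency list had a median of -2.94 and 6 of its 10 members lower by size, among them SOX2 (-4.06), POU5F1 (-3.69, from 602 CPM in hPSC to 45.6 in DE) and the DNA methyltransferase DNMT3B (-3.45). The unfolded protein response list had a median of 1.05, with 12 of 14 members above 0 and 0 different by size. TXNIP, an inhibitor of thioredoxin and of glucose uptake, stood at -7.16 and SFRP2, a WNT antagonist, at -5.47. The hPSC library also held reads of genes of later stages: GCG, the glucagon gene, at 85.5 CPM, TTR at 59.6 CPM and CHGA at 49.4 CPM, against 0.422, 0.613 and 2.16 CPM in DE. Of 9201 genes, 521 were higher and 342 lower by size, meaning a log2 ratio of at least 2 with at least 20 CPM in the higher library. With a minimum of 5 CPM, 1408 genes were different.

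From DE to PP1, endoderm genes gave way to genes of gut tube and pancreas. CER1 stood at -11.73, LEFTY2, a Nodal inhibitor, at -10.43, EOMES at -8.71 and SOX17 at -7.53. The definitive endoderm list had a median of -5.13, with 8 of 11 members lower by size. IGF2, a fetal growth factor, stood at 10.66, TTR at 7.98, MTTP, which loads lipid onto apolipoprotein B, at 7.94 and CYP26B1, which degrades retinoic acid, at 7.48. The pancreatic progenitor list had a median of 2.32, with 4 of 8 members higher by size, among them ONECUT1 at 5.22. PDX1, the pancreatic master regulator, was at 67.99 CPM in PP1 and 0.0128 CPM (1 read) in DE. The glycolysis list had a median of -2.16, with 10 of 16 members lower by size, including LDHA (-4.87), HK2 (-3.14) and ALDOA (-2.85). The hypoxia list had a median of -1.35, with 3 of 10 members lower by size. The cholesterol synthesis list had a median of -0.97, with 0 of 17 members above 0 and 2 lower by size. Of 9398 genes, 451 were higher and 421 lower by size, and 1395 were different with a minimum of 5 CPM. TMM scaling shifts the median of all genes here by -0.11.

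From PP1 to PP2, NKX6-1 and several other genes of progenitor and endocrine cells were higher. NKX6-1, a transcription factor of the beta lineage, stood at 7.34 (0.0833 CPM in PP1 and 174 CPM in PP2). SOX9, a progenitor and duct transcription factor, stood at 3.98, the trypsin inhibitor SPINK1 at 6.64 and the Notch ligand family member DLK1 at 5.01. SST stood at 5.67 and CHGA, a granin of endocrine granules, at 4.68. The beta cell identity list had a median of 2.76, with 14 of 15 members above 0, 4 higher and 1 lower by size. Of 13 immediate early genes, 12 were above 0 and 5 higher by size (median 1.503), among them FOS (4.38), FOSB (4.08) and EGR1 (3.18). All 17 members of the cholesterol synthesis list were above 0 (median 0.56) and 0 passed the size minimum. CYP26A1, which degrades retinoic acid, stood at -7.46, APOA2 at -5.94, and the hindbrain-associated HOXB1 at -4.9996. The ribosomal protein list had a median of -0.75, with 0 of 24 members above 0. Of 9337 genes, 212 were higher and 135 lower by size, and 599 were different with a minimum of 5 CPM. TMM scaling shifts the median of all genes by -0.10.

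From PP2 to EN, endocrine genes were higher and genes of progenitors and of the cell cycle were lower. INSM1, an endocrine transcription factor, stood at 6.02, and NEUROG3, the transient switch of endocrine fate, at 5.54 (5.55 CPM in PP2 and 303 CPM in EN). The endocrine progenitor list had a median of 4.60, with 8 of 10 members higher by size. The enterochromaffin-like list had a median of 4.57, with 5 of 7 members higher by size, including TPH1 (5.602), which starts serotonin synthesis, the vesicular monoamine transporter SLC18A1 (5.85) and FEV (4.57). Of 16 exocytosis genes, 11 were higher by size (median 2.53), among them SYT4 (5.21) and SYT7 (5.02). GCG stood at 4.08 and INS at 2.71. SOX9 stood at -4.82, ACSM3 at -7.06 and SCTR, the secretin receptor, at -5.69. The proliferation list had a median of -2.07, with 8 of 12 members lower by size, such as RRM2 (-3.79) and BIRC5 (-3.34). Of 9721 genes, 573 were higher and 522 lower by size.

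From EN to SCbeta, hormone and beta cell genes were higher. IAPP, which encodes amylin, stood at 9.58, INS, the insulin gene, at 6.14 (59.8 CPM in EN and 4274 CPM in SCbeta), the islet glucose-6-phosphatase G6PC2 at 4.36 and the calcium-sensing receptor CASR at 6.08. The beta cell identity list had a median of 1.55, with 7 of 17 members higher and 1 lower by size. The core clock list had a median of 0.72, the 100th percentile of random lists matched on expression, with 16 of 20 members above 0 and 2 higher by size, PER3 (3.48) and the PAR-bZIP factor HLF (3.23). Genes encoded in mitochondrial DNA took 9.26% of assigned reads in SCbeta and 3.62% in EN, so RNA or library quality is not separated from the cell type. NEUROG3 stood at -5.85, SOX4 at -3.63 and the pluripotency-associated L1TD1 at -6.73. The endocrine progenitor list had a median of -2.05, with 5 of 10 members lower by size. Of the enterochromaffin-like list, 3 of 7 members were lower by size (median -1.98), among them SLC18A1 (-4.35) and TPH1 (-2.96). MAFA was near the floor in both libraries (1.51 CPM in SCbeta, 2.34 in EN). Of 9320 genes, 346 were higher and 503 lower by size, so 40.8% of the different genes were higher. With TMM scaling that share was 56.9%, and the median of all genes shifted by 0.31. With a minimum of 5 CPM, 1370 genes were different.

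Beta and poly-hormonal cells of the same stage and day differed in hormone genes. INS stood at 3.59 in SCbeta relative to PH (4274 and 354 CPM), IAPP at 3.03, the prohormone convertase PCSK1 at 2.28 and PDX1 at 2.25. GCG stood at -3.06. The beta cell identity list had a median of 0.91, with 15 of 17 members above 0 and 5 higher by size. The alpha cell list had a median of -1.08, with 3 of 13 members lower by size. The enterochromaffin-like list had a median of -2.35, with 0 of 7 members above 0 and 3 lower by size, and the proliferation list -1.56, with 3 of 12 lower. The core clock list had a median of -0.56 (percentile 0), with 4 of 20 members above 0 and 1 lower by size, NPAS2 (-3.49), a partner of ARNTL. Of 8529 genes, 69 were higher and 70 lower by size (49.6% higher), and with TMM scaling 62.9% were higher, with the median of all genes shifted by 0.16. The count of 139 different genes became 82 with 5 CPM added in place of 1, and 220 with a minimum of 5 CPM.

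Relative to adult beta cells, SCbeta held lower levels of genes of mature beta function. MAFA, a transcription factor of mature beta cells, stood at -5.27 (1.51 and 95.7 CPM), G6PC2 at -4.60, UCN3, a peptide of mature beta cells, at -3.43, IAPP at -2.73 and INS at -1.63. The beta cell maturation list had a median of -2.50, with 7 of 15 members lower by size. The core clock list had a median of -0.77 (percentile 0), with 3 of 21 members above 0, 1 higher and 5 lower by size, among them BHLHE40 (-4.67), NPAS2 (-4.07) and BHLHE41 (-4.05). SPP1, which encodes osteopontin, stood at -9.56, TGM2 at -8.39 and PTGS2, a prostaglandin synthase, at -6.86. Higher in SCbeta were PAX4 (6.28), a factor of the beta lineage, the peptidase DPP4 (5.13), GCG (3.71) and CHGA (3.36), and APOB was at 321 CPM with 0 reads in Beta. The alpha cell list had a median of 3.27, with 7 of 13 members higher by size. The cholesterol synthesis list had a median of 1.36, with 5 of 17 higher by size, such as HMGCS1 (3.73). Of 8747 genes, 688 were higher and 348 lower by size. With a minimum of 5 CPM, 1725 genes were different, and TMM scaling shifts the median of all genes by -0.17.

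Adult alpha and beta cells served as the reference pair. GCG stood at 8.15 in Alpha relative to Beta, the vitamin D binding protein GC at 7.18, the protease FAP at 7.31 and the transcription factor IRX2 at 6.92. INS stood at -4.77, MAFA at -3.23, PDX1 at -3.22 and IAPP at -2.85. The alpha cell list had a median of 5.89, with 12 of 13 members higher by size. The beta cell identity list had a median of -1.66, with 7 of 17 members lower and 1 higher. Immediate early genes had a median of 1.28, with 3 of 13 higher by size, the nuclear receptors NR4A1 (2.23), NR4A2 (2.88) and NR4A3 (3.74) being beyond 2 in size. Genes encoded in mitochondrial DNA took 3.50% of assigned reads in Alpha and 7.49% in Beta, so RNA or library quality is not separated from the cell type. The core clock list had a median of 0.05, with BHLHE41 (-2.46) the 1 member different by size. Of 7735 genes, 252 were higher and 194 lower by size, and 709 were different with a minimum of 5 CPM. TMM scaling shifts the median of all genes by -0.10. A difference by size is a difference between 2 libraries, in which preparation and cell type are not separated.

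**Figure D1:**
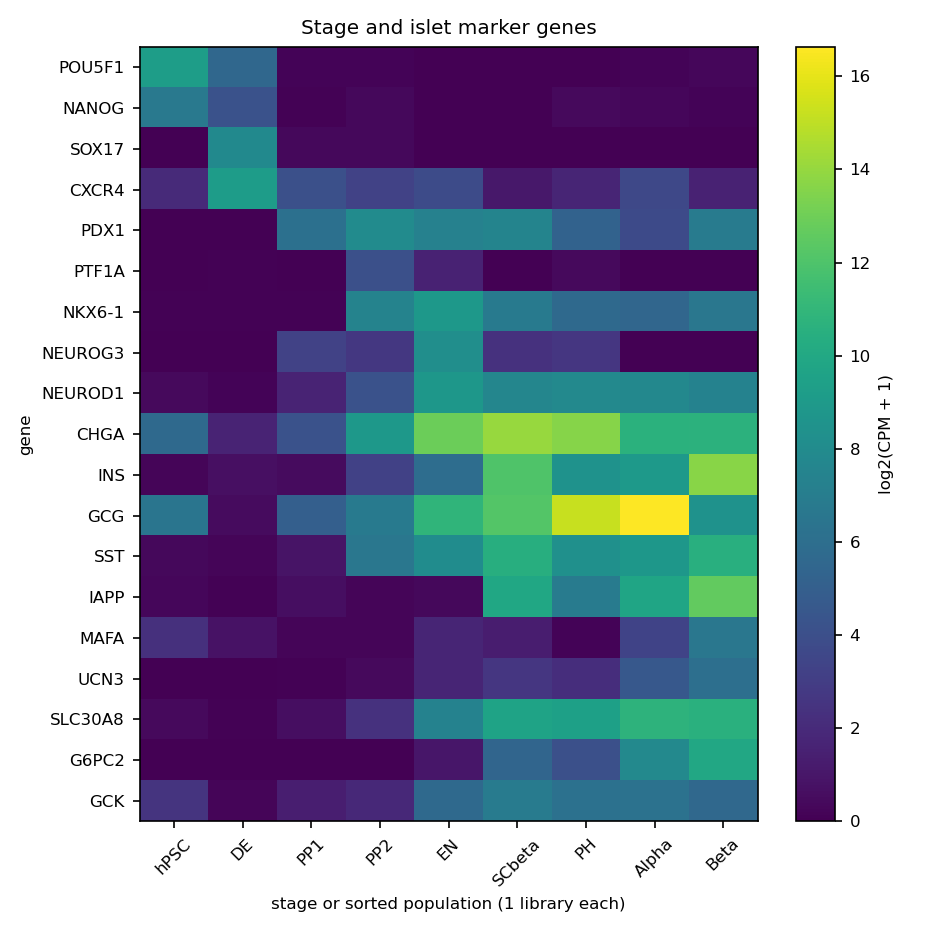
Heat map of log2(CPM + 1), shown by colour, for 19 stage and islet marker genes (vertical) in the 9 purified cell libraries (horizontal, 1 library each, no replicates). INS stands at 59.8 CPM in endocrine progenitors and at 4274 CPM in stem-cell-derived beta cells.

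SC islets were compared with primary islets over the 14 entrained times that both have. Each value is the mean log2 ratio of the 3 SC series to the 1 primary series, with the SD over the SC series (n = 3). Genes of stroma and vessels were lower in SC islets: COL6A3 stood at -9.18 ± 0.89, COL3A1 at -8.65 ± 0.88 and COL1A1 at -7.05 ± 0.20, all collagens, and the endothelial PECAM1 at -5.28 ± 0.14. The mesenchymal list had a median of -5.34, with 8 of 9 members lower by size, and the endothelial list a median of -4.67. SPP1 stood at -8.86 ± 0.99 and CRP, an acute phase protein, at -8.92 ± 0.81. Genes of mature beta cells were lower too: MAFA stood at -6.94 ± 0.13 (0.400 and 127 CPM), G6PC2 at -5.04 ± 0.30, IAPP at -4.90 ± 0.55, UCN3 at -3.64 ± 0.75 and INS at -1.22 ± 0.30. The beta cell maturation list had a median of -3.40, with 9 of 15 members lower and 1 higher by size. SST stood at -3.92 ± 0.58, and GCG at -0.29 ± 0.41, within the spread between series. Higher in SC islets were the serotonin genes TPH1 (7.13 ± 0.14) and SLC18A1 (6.68 ± 0.09), and 6 of 7 members of the enterochromaffin-like list, with a median of 4.22. The exocrine genes CLPS (7.58 ± 0.32) and CEL (7.12 ± 0.64), the RNA-binding fetal gene IGF2BP1 (7.02 ± 0.13), neurotensin (NTS, 7.25 ± 1.08) and CHGA (3.39 ± 0.07) were higher as well. The acinar list was mixed, with 3 of 9 members higher and 1 lower by size, REG1A (-7.49 ± 0.76), and a median of 1.396. The proliferation list had a median of 2.01, with MKI67 at 3.00 ± 0.08, and all 17 cholesterol synthesis genes were above 0, with a median of 1.10. Of the core clock list, 5 of 21 members were lower by size (median -0.84), among them BHLHE40 (-3.68 ± 0.38), NPAS2 (-2.72 ± 0.37) and BHLHE41 (-2.57 ± 0.24). Of 8978 genes, 337 were higher and 481 lower by size in all 3 series. No test was made, since the primary islets are 1 series.

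**Figure D2:**
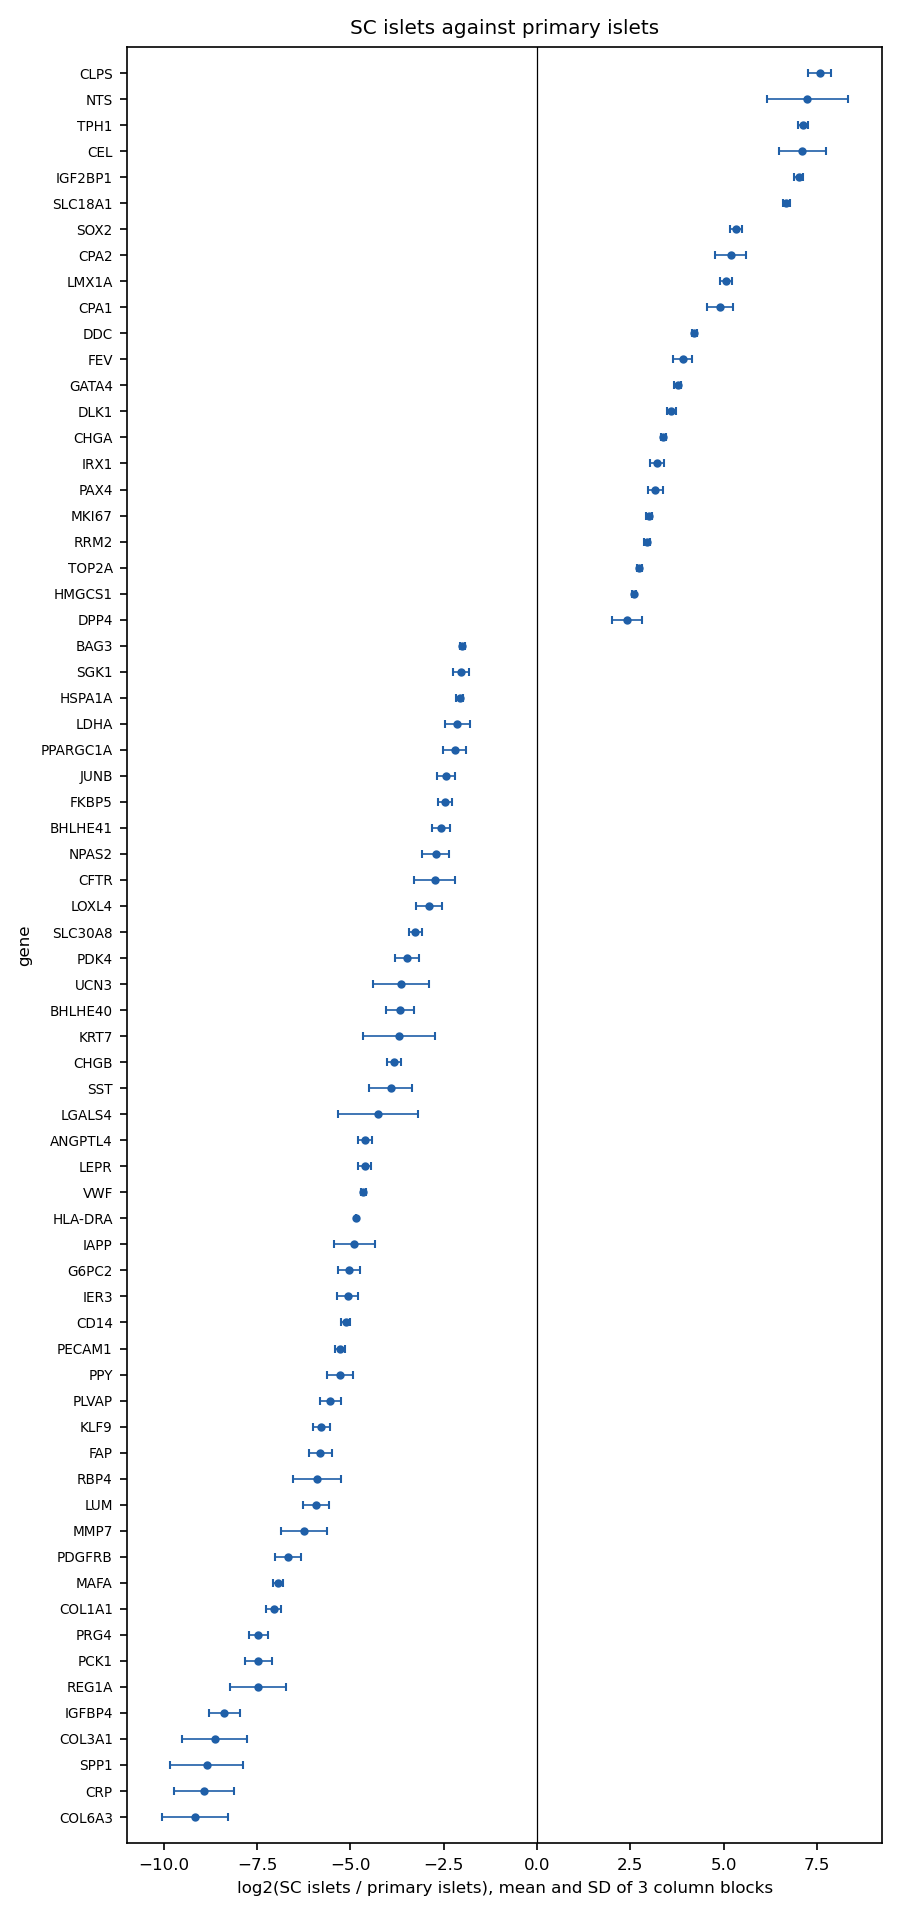
Log2 ratio of entrained SC islets to entrained primary islets (horizontal) for named genes (vertical), with points for the mean and bars for the SD of the 3 SC series. MAFA, at -6.94, and TPH1, at 7.13, lie on opposite sides of 0.

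The rhythm comparisons ask which genes follow a 24 h cycle in entrained islets and whether mock islets follow it too. Sizes are given as the swing, the fitted log2 difference between peak and trough, with the SD over the series' own fits (n = 3). Before any gene is named, a feature of the libraries stands beside every count: the dependence on GC content differed between times of day. Across genes, the correlation of GC content with a library's deviation from the arm's mean had a median of -0.746 at CT4 and -0.6675 at CT8 in the entrained SC islets, and of 0.357 to 0.70045 at the other times of day. The mock SC islets had medians of -0.630 and -0.786 at those times and 0.378 to 0.621 at the others. The primary islets had -0.806 and -0.577, then 0.610 at CT12 and 0.694 at CT16, but -0.186 at CT0 (-0.208 to 0.603 over 3 libraries), unlike the SC islets at that time. Library pools nearly follow the time of day as well. Therefore counts over all genes are given with and without a correction for GC content, which was chosen after seeing the data. Swings and peaks of several clock genes are given with the correction alone, as stated there.

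**Figure D3:**
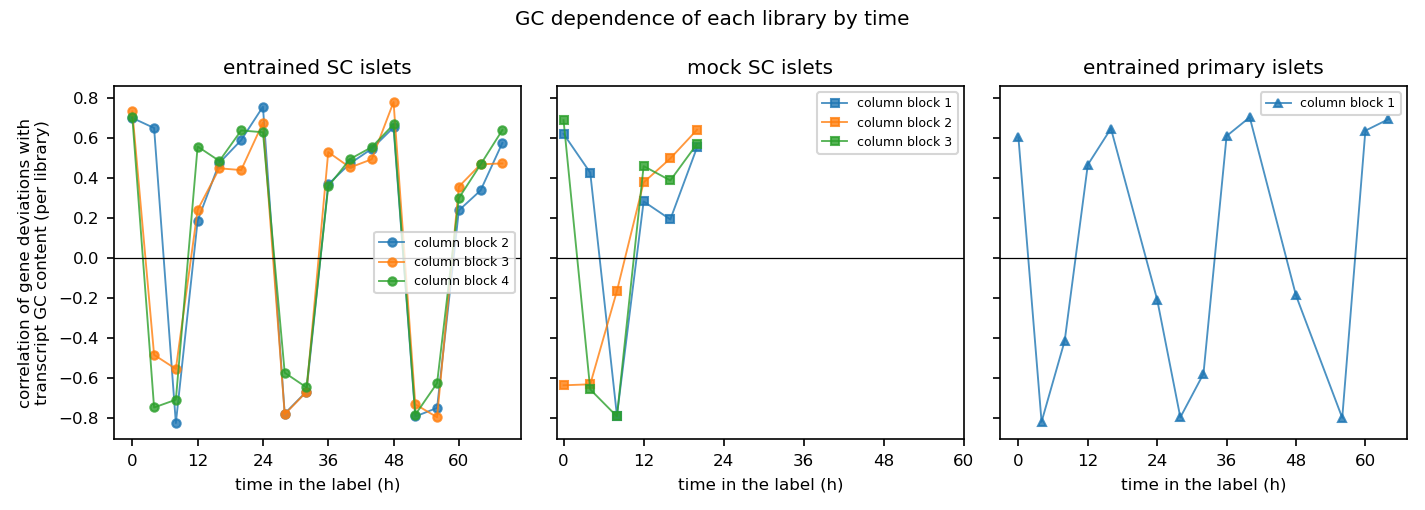
Correlation across genes between GC content and each library's deviation from the mean of its arm (vertical), against the labelled time in hours (horizontal), with 1 point per library and 1 line per column block. Medians lie at -0.746 for CT4 and 0.70045 for CT0 in the entrained SC islets, and 3 SC libraries have the sign of other times of day.

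In entrained SC islets, most core clock genes passed the test of a 24 h component, as did most genes. After the GC correction NR1D1, the REV-ERB alpha repressor, had a swing of 1.19 ± 0.06 with its peak at 23.3 h (adjusted p = 2.84e-09, limma). Its paralog NR1D2 had 0.72 ± 0.20 and 3.38 h, CIART, a repressor of CLOCK and ARNTL, 0.79 ± 0.12 and 1.25 h, PER3 0.52 ± 0.07 and 2.74 h, the PAR-bZIP factor DBP 0.57 ± 0.16 and 5.25 h, and PER2 0.35 ± 0.03 and 7.12 h. CRY1 peaked later, at 13.03 h (0.28 ± 0.11), followed by ARNTL, the BMAL1 activator, at 16.4 h (0.32 ± 0.08) and NPAS2 at 18.7 h (0.41 ± 0.11). Of the 20 core clock genes tested, 16 passed the test after the correction (16 adjusted over the list alone) and 17 before it. Without the correction the peaks of some differ: DBP stood at 19.6 h, and ARNTL (adjusted p = 0.127) and PER2 (adjusted p = 0.705) did not pass. INS had a swing of 3.55 ± 0.33 without the correction and 1.84 ± 0.19 with it, peaking at 18.4 and 18.3 h, and SST had 1.33 ± 0.19 and 0.92 ± 0.20. GCG (0.53 ± 0.05), UCN3 (1.07 ± 0.32) and CLOCK (0.59 ± 0.04) passed the test only without the correction, with which their adjusted p were 0.118, 0.408 and 0.155. MAFA, at 0.411 CPM, was not tested. With the GC correlation of each library as a term in place of the correction, NR1D1, CIART, PER3 and CRY1 kept their direction and passed (swings along the uncorrected peak of 0.29, 0.76, 0.26 and 0.20), ARNTL (adjusted p = 0.201), NPAS2 (0.163) and DBP (0.146) did not pass, and the swing turned against the uncorrected peak for NR1D2 (-0.03), INS (-0.23, with a whole swing of 0.56) and SST (-0.33). The genes of smallest p that peaked alike in each series include several of high GC content: PCSK1N, a proconvertase inhibitor (swing 3.97 ± 0.73, GC content 65.04%), C4orf48 (3.98 ± 0.77, 73.9%), CTXN1 (3.48 ± 0.57, 72.8%) and NPW, a neuropeptide gene (3.46 ± 0.56, 72.05%), all with peaks between 18.5 and 18.7 h. With the correction NPW had a swing of 1.74 and PCSK1N of 2.25, while NR2F6 went from 1.72 to 0.04. HTATSF1, a splicing-linked factor, peaked at 5.73 h with 1.03 ± 0.16 (GC content 47.95%) and had 0.83 with the correction.

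Over the genome, 12760 of 15882 genes, 80.3%, passed the test in the 54 entrained SC libraries, 8691 of 15836 with the GC correction, 6361 with the GC correlation of each library as a term, 12019 with the pool group as a term (pools 1 and 2 against 3 and 4) and 6898 with a swing of at least 1.5-fold required. The pool group parts CT0, CT4 and CT8 from the other hours, so it cannot take up differences within either group. Of the uncorrected calls, 34.4% peaked between 4 and 8 h and 42.3% between 16 and 20 h. No gene list was overrepresented among called genes (0 lists past an adjusted p of 0.05, Fisher's exact test), the core clock list having an adjusted p of 0.948 without and 0.272 with the correction. With 80.3% of all genes called, the uncorrected test had little room to find a short list overrepresented, so it decides nothing.

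**Figure D4:**
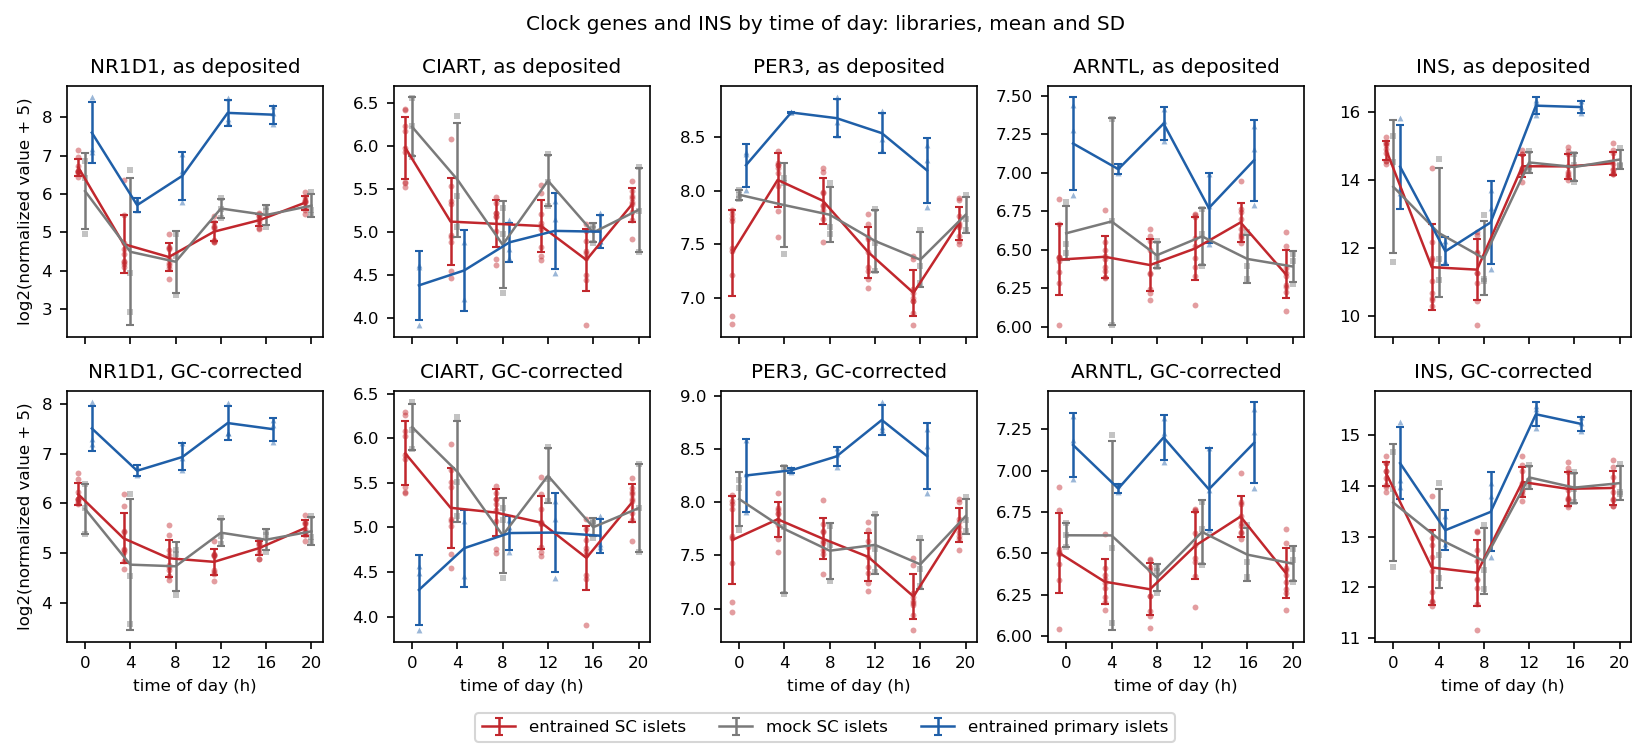
Log2(normalized value + 5) of 4 clock genes and INS (vertical) against the time of day in hours (horizontal), before (top) and after (bottom) the GC correction, with points for libraries and lines and bars for the mean and SD over libraries of an arm. After the correction NR1D1 has a fitted swing of 1.19 in entrained SC islets with its peak at 23.3 h, and ARNTL one of 0.32 at 16.4 h.

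Over CT0 to CT20 the arms can be set side by side, with 18 libraries each. In entrained SC islets, CIART (swing 1.11, peak 3.18 h, adjusted p = 0.0439), NR1D1 (1.36, 0.415 h, adjusted p = 0.0146) and PER2 (0.55, 9.39 h, adjusted p = 0.0407) passed after the GC correction, and 5 of 20 core clock genes adjusted over the list alone. In mock SC islets 0 of 20 core clock genes passed (limma), with or without the correction and adjusted over the list alone. There NR1D1 had a corrected swing of 0.79 and a peak at 19.9 h (adjusted p = 0.356), NR1D2 0.12, PER2 0.18, CIART 0.70 at 0.984 h and ARNTL 0.05. INS in mock islets had 2.81 without and 1.46 with the correction (adjusted p = 0.0676 and 0.0906). In all, 3018 of 15869 genes passed in entrained islets over these times and 466 of 15912 in mock islets. Both counts depend on the processing: with edgeR they were 172 and 124 (RLE scaling) or 171 and 1 (TMM scaling, chosen after seeing the data), with the GC correction 376 and 539, with the pool group as a term 0 and 0, without the libraries of the other GC sign 6609 and 5030, and without 1 series they went from 0 to 845 and from 0 to 1062. Without libraries under 1500000 reads the mock count was 2597. Called genes overlapped more than independent lists would: 291 against 89.2 expected, or 129 against 12.9 with the correction. Of the 465 genes called in mock islets that were tested in both arms, 97.0% peaked in entrained islets within 4 h of their mock peak. Peaks spread evenly over the day would give 33.3%. Shared peak hours raise the agreement of peaks, since 64.6% of entrained and 60.1% of mock calls peaked between 16 and 20 h. How much of the agreement they account for was not tested.

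The difference in rhythm between arms was tested directly. It was found for 0 of 15937 genes by limma, with 212 at an unadjusted p under 0.05, and for 0 by edgeR and under every other setting run. Without a correction 1 core clock gene, PER3, was at an unadjusted p under 0.05. After the GC correction there were 5 of 20 (NR1D1, NR1D2, PER2, PER3 and CRY2), and 0 adjusted over the list alone. Among the 10 genes of smallest p were STC1, the stanniocalcin gene (swing of the difference 0.74), the gonadotropin alpha subunit CGA (1.36) and CCDC80 (0.96), none past the adjustment. Simulated differences of 1 log2 were called for only 4 of 200 genes, so a difference of that size was not detectable at this depth and number of libraries.

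In the 14 entrained primary libraries, HLF had a swing of 1.13 with its peak at 5.14 h (adjusted p = 0.000907) and 1.02 at 5.30 h after the GC correction (adjusted p = 0.00678), and RORA, a nuclear receptor of the clock, 1.40 and 1.30 (adjusted p = 0.00879 and 0.0458). NR1D1 had 2.39 at 17.2 h and 0.87 after the correction (adjusted p = 0.134), PER1 2.95 and 0.88 (adjusted p = 0.0585). Of 21 core clock genes, 14 passed without the correction (15 adjusted over the list alone) and 2 with it (4 adjusted over the list alone). INS had 4.64, and 2.30 with the correction, SST 2.18 and 1.46. MAFA had 0.78 with its peak at 16.6 h, and 1.56 at 4.76 h after the correction. Genes of smallest p were again of high GC content, such as MIF, a cytokine (4.60, GC content 67.1%), LAMA5, a basement membrane laminin (3.69, 64.6%), and AGRN, the agrin gene (3.60, 66.2%). They had 2.28, 1.35 and 1.26 with the correction. Of 15856 genes, 7906 passed, 1184 with the GC correction, 0 with the GC correlation of each library as a term, where INS, NR1D1, PER1 and RORA turned against their peak (-0.50, -0.81, -0.38 and -0.43), and 1 with the pool group as a term. The series is 1 preparation per time, so the test measures spread between libraries and not between preparations. It has no library at CT20, CT44 or CT68, so that time of day is not sampled. Of its uncorrected calls 0.202% peaked between 8 and 12 h and 0.177% between 20 and 24 h. In entrained SC islets these shares were 12.3% and 6.99%.

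The rhythm of primary islets differed from that of SC islets for 6468 of 16248 genes, for 2041 with the GC correction, for 1501 with the GC correlation as a term and for 6755 with the pool group as a term. Without SC block 2 it was 3161 and without SC block 4 4308. Of 21 core clock genes, 9 differed, or 4 with the correction, among them NR1D1 (adjusted p = 0.00154, and 0.00238 corrected), CIART (0.00316 and 0.00532), PER1 (0.00861 and 0.0155) and PER3, which passed with the correction alone (0.182 and 0.00826). CIART peaked at 1.25 h in SC islets and at 10.8 h in primary islets after the correction, the latter fit not passing the test. For PPP1R3B, a glycogen-targeting phosphatase subunit, the swing of the difference was 0.91, and 0.98 with the correction. Of the 10 genes of smallest p, 9 were under 0.2 CPM in SC islets, for example REG3A, FLG and LGALS1, so that their difference is the swing of the primary islets alone.

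Entrained and mock SC islets were compared over CT0 to CT20, with the mean of each series as 1 value (n = 3 per arm). Immediate early genes stood higher in entrained islets: all 12 members were above 0, with a median log2 difference of 0.49, and 6 passed adjusted over the list alone. The list passed camera (adjusted p = 3.29e-11), but not with an estimated correlation (adjusted p = 0.227 with an estimated correlation). Targets of cAMP and CREB had 10 of 12 members above 0, a median of 0.30 and 3 members past the test adjusted over the list alone (adjusted p = 1.08e-06, and 0.227 with an estimated correlation). Members of these 2 lists include the kinase SIK1 (1.22 ± 0.21 SE), the phosphodiesterase PDE10A (0.85 ± 0.18), NR4A1 (0.79 ± 0.22) and IER3 (0.80 ± 0.20). SGK1, a glucocorticoid-induced kinase, stood at 1.60 ± 0.23 and DUSP1, a MAP kinase phosphatase, at 0.47 ± 0.12, and the glucocorticoid target list had 2 members past the test adjusted over the list alone (adjusted p = 0.00945, and 0.227 with an estimated correlation). All 24 ribosomal protein genes were below 0 (median -0.14, adjusted p = 3.98e-11, and 0.299 with an estimated correlation). Glycolysis genes had 13 of 16 above 0 (median 0.14, adjusted p = 0.00032, and 0.227 with an estimated correlation) with LDHA at 0.53 ± 0.20. The list of glucose-responsive ChREBP targets had 4 of 7 members past the test adjusted over the list alone: TXNIP at 0.51 ± 0.17 and G6PC2 at -0.72 ± 0.27 went opposite ways (adjusted p = 0.0106, and 0.299 with an estimated correlation). Duct markers, of another cell type, had 7 of 7 above 0 (median 0.64, adjusted p = 0.00503, and 0.496 with an estimated correlation), with KRT7 at 0.92 ± 0.47. The acinar gene CPA1 stood at 0.88 ± 0.23 and the mesenchymal gene COL1A1 at 1.01 ± 0.22.

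Hormone genes lay within the spread of the series: INS stood at 0.03 ± 0.21, GCG at -0.12 ± 0.25, SST at 0.33 ± 0.33, IAPP at 0.31 ± 0.31 and UCN3 at -0.26 ± 0.53. The beta cell identity list had a median of 0.02 (adjusted p = 0.95), 11 of 17 members above 0 and 1 past the test adjusted over the list alone. SLC30A8, the zinc transporter of insulin granules, stood at -0.38 ± 0.11. The core clock list had a median of -0.03 (adjusted p = 0.116) and 0 of 20 members past the test, with BHLHE41 at -0.52 ± 0.19. Genes of smallest p, chosen after their values were seen, were ECEL1, a membrane peptidase (2.17 ± 0.19, adjusted p = 0.059), G0S2, a lipase inhibitor (1.49 ± 0.15, adjusted p = 0.0593), KRT17 (2.35 ± 0.31), CXCL5 (1.66 ± 0.26), IGFBP3 (0.74 ± 0.12), RGS9 (0.65 ± 0.09), the amino acid transporter SLC38A2 (0.49 ± 0.08) and SLC16A9 (-0.66 ± 0.11). All of these had the same sign in 9 of 9 pairs of series. By limma 0 of 15937 genes passed, with 769 at an unadjusted p under 0.05, 0 by edgeR, 2 by limma after TMM scaling and 117 by DESeq2. A fit of all 36 libraries with time of day as a term and the series as a random effect, chosen after seeing the data, called 195, of which 71 were also among the 117. Without entrained block 4 limma called 2. The arms did not overlap for 834 genes that were higher and 762 that were lower in entrained islets, 10.0% of those tested, where chance gives 10% without pairs. If the series of both arms are paired, as their shared numbers in the titles allow, the share that chance gives can differ, and it was not computed. Of 31 lists tested, 16 passed camera with its preset correlation, 0 with an estimated one and 0 fry for a shared direction. The mixed test of fry, which takes changes in either direction, passed for glucocorticoid targets (adjusted p = 0.0039), immediate early genes (0.037) and glucose-responsive ChREBP targets (0.037).

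**Figure D5:**
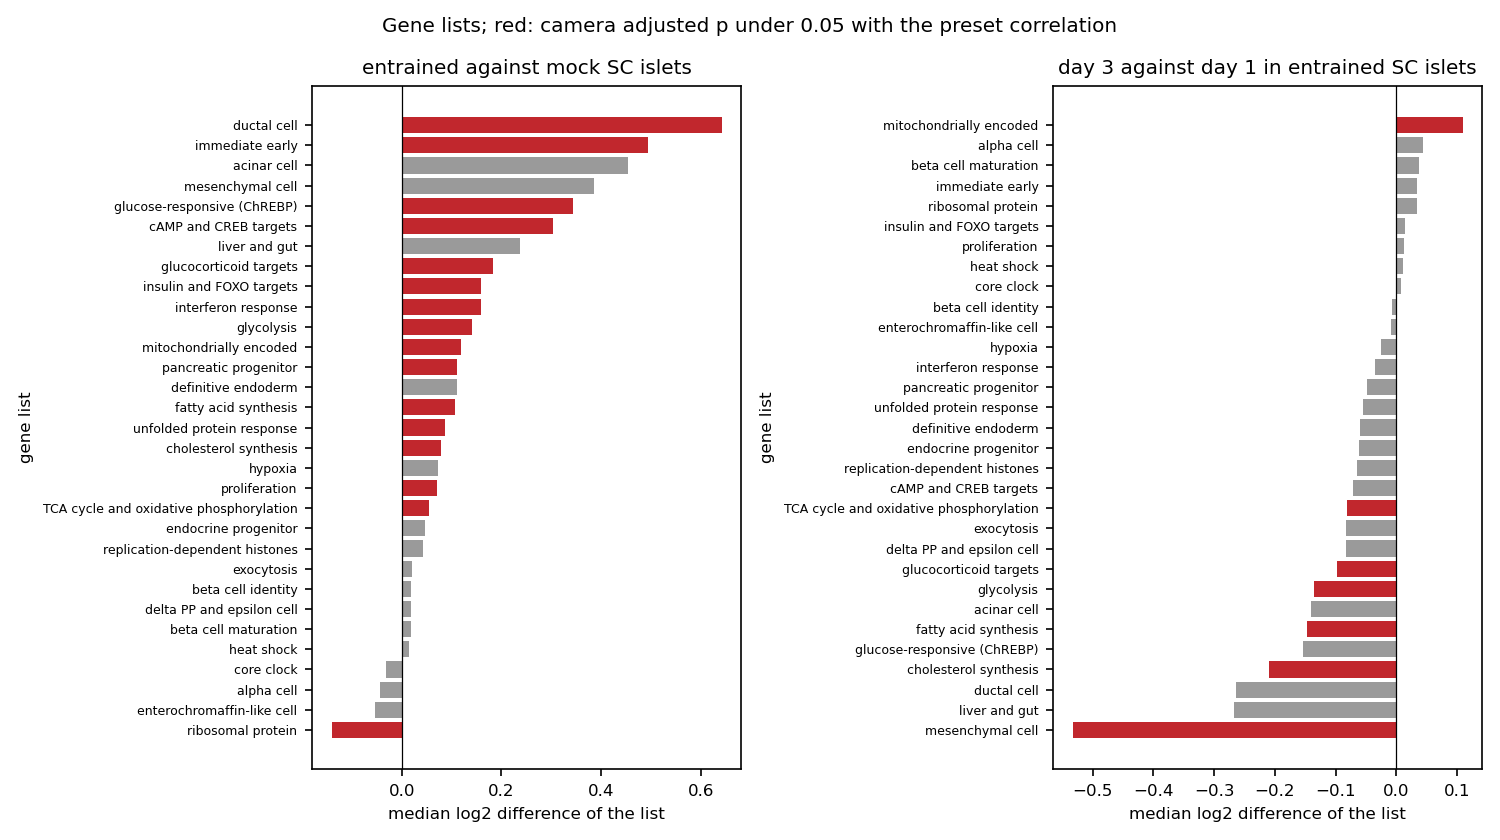
Median log2 difference of each gene list (bars) for entrained against mock SC islets (left) and day 3 against day 1 of entrained SC islets (right), in red where camera passed with its preset correlation. Immediate early genes lie at 0.49 on the left and 0.03 on the right, and cholesterol synthesis genes at 0.08 and -0.21.

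Day 3 (CT48 to CT68) of the entrained SC islets was compared with day 1 (CT0 to CT20), with 3 series each. With the column block as a term, cholesterol synthesis genes were lower on day 3, with 6 of 17 members past the test, all falling, for example DHCR7 (fell by 0.36). That list passed camera without the block (median -0.21, 2 of 17 above 0, 5 past the test adjusted over the list alone, adjusted p = 5.6e-08, and 0.319 with an estimated correlation). Glycolysis had 3 members that fell, HK1, TPI1 and PKM, and a median of -0.14 (adjusted p = 1.57e-05, and 0.319 with an estimated correlation). Fatty acid synthesis had 2 members that fell and a median of -0.15 (adjusted p = 5.11e-05, and 0.319 with an estimated correlation). Genes of the TCA cycle and oxidative phosphorylation had a median of -0.08, with 0 members past the test (adjusted p = 0.0003, and 0.319 with an estimated correlation). Genes encoded in mitochondrial DNA had 12 of 13 above 0 (median 0.11, adjusted p = 0.0164, and 0.909 with an estimated correlation). Of the immediate early genes 3 rose, FOSB (0.85 ± 0.48 SD), EGR1 (0.73 ± 0.42) and FOS (0.41), while the list as a whole did not pass (adjusted p = 0.175). The helix-loop-helix inhibitors ID1 (1.26 ± 0.34, adjusted p = 0.00095), ID3 (0.92 ± 0.39) and ID2 (0.59 ± 0.14), which BMP signalling induces, rose. BHLHE41 rose by 0.50 ± 0.25 (adjusted p = 0.0444), the 1 core clock gene called, and G6PC2 by 0.44. G0S2 fell by 1.49 ± 0.33 (adjusted p = 0.000661), ECEL1 by 1.29, KRT17 by 1.27, FGB by 0.99 ± 0.18 and SGK1 by 0.74, TXNIP by 0.64 and the guanylate cyclase ligand GUCA2B by 1.30. Markers of other cell types fell as well: 2 of 7 duct markers, KRT7 (fell by 0.59) and CFTR (fell by 0.53), 1 of 7 acinar markers, PRSS1 (fell by 0.31), and 1 of 4 mesenchymal markers, COL1A1 (fell by 0.91). GP2, a zymogen granule protein outside the lists, fell by 0.83 ± 0.09.

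The values of single genes come from the fit with the column block as a term, and the medians and adjusted p of lists from the fit without it. The fit with the block called 348 genes, 161 higher and 187 lower. Without the block limma called 0 of 15885, with 1220 at an unadjusted p under 0.05, edgeR 1 and DESeq2 35, of which 29 were among the 348. In the fit with the block the lists that passed camera had adjusted p of 0.688 to 0.74 with an estimated correlation. The days did not overlap for 1335 genes that were higher and 1004 that were lower on day 3, 14.7% of those tested, where chance gives 10% without pairs. Both days come from the same 3 series, so the share that chance gives here can differ from 10% and was not computed. The day 1 libraries are those of the comparison of arms, so the signs of both comparisons are not independent.

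Entrained and mock primary islets could be compared at CT16 alone, 1 library each (3160827 and 3911139 reads). Endothelial and mesenchymal genes were higher in the entrained library, with list medians of 0.99 and 0.82 and all 9 mesenchymal genes above 0, for example VWF (1.36), PECAM1 (1.31) and PDGFRA (1.38). The alpha cell list had a median of -0.73, with GCG at -0.96, and the beta cell identity list -0.37, with INS at -0.61, IAPP at -0.78, UCN3 at -0.83 and MAFA at 0.05. Immediate early genes had 11 of 13 above 0 (median 0.52), including NR4A1 (1.24), and cAMP and CREB targets 10 of 12 (median 0.66). PER3 stood at -0.90 and HLF at -0.88, and the core clock list at a median of -0.11. Of 7459 genes, 6 were higher and 6 lower by size, among them the hyaluronan-binding CEMIP (2.86), the protease ADAMTS4 (2.43), the VEGF receptor FLT1 (2.17), IL24 (2.16), the mucin MUC5B (-2.56) and PPY, the pancreatic polypeptide gene (-2.25). Genes encoded in mitochondrial DNA were lower in the entrained library (median -0.66, 0 of 13 above 0), and the non-coding RN7SL1 and RN7SL2 took a smaller share of its reads, so a difference in RNA or library quality is not separated from the arm. With 1 library per arm, no test was made.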

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

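The tests of GC content, of the INS swing and of the swings of clock genes between arms, and the splits in the corrected fits, were chosen only after the result was seen, except the GC test on the clock genes' difference between arms. The other splits and orderings of the samples, and the comparison of mock with entrained swings, were chosen before.

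The rhythm of primary islets differed from that of SC islets by a test of the difference itself for 6468 genes, a difference between groups that marks each of the following results. The swing of the difference was 1.02 for CLOCK, 2.34 for PER1, 2.44 for NR1D1, 1.11 for RORA, 1.16 for DBP, 1.03 for TEF, 0.84 for HLF and 1.63 for CIART among clock genes. Among hormone genes it was 2.51 for INS, 0.76 for GCG, 1.41 for SST and 0.71 for IAPP, but with the GC correction none of these 4 passed and GCG (-0.052), IAPP (-0.017) and the clock gene DBP (-0.019) turned direction, as INS (-0.12) did with the GC correlation as a term. Among the 10 genes of smallest p it was 2.47 for BARHL1, 2.43 for C11orf96, 2.34 for FLG, 2.73 for HTRA3, 3.78 for LAMC3, 2.72 for LGALS1, 2.04 for LYNX1, 2.17 for PDZK1IP1, 0.91 for PPP1R3B and 2.15 for REG3A. With the GC correction 2041 genes differed, among them 4 of 21 core clock genes against 9 without it, and with the GC correlation of each library as a term 1501, and the primary islets are 1 series, so preparation is not separated from system.

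A 24 h component was called for 12760 genes of the entrained SC islets, and of the 60 orderings of the 6 times of day 18 gave as many called genes, the highest of the others 13700, so the order of the times does not set the real one apart. Mock islets had a median swing of 82.2% of that of entrained islets over CT0 to CT20 along the phase of the later days (11715 genes), which argues against entrainment as the whole of the pattern. In 3 SC libraries (entrained block 2 at CT4, mock block 1 at CT4 and mock block 2 at CT0) the GC correlation has the sign of other times of day, and across the called genes their deviations correlate with the other libraries of their time at -0.794, -0.551 and -0.613, the highest being -0.551, while the other 69 libraries lie between 0.373 and 0.937. The 3 libraries were picked by that sign, which comes from the same deviations, so values below 0 were largely fixed by the choice. A shift of whole libraries along GC content needs such values, but a wrong time label on these libraries under a true rhythm would give them too, so they do not favour either. The shift, which nearly follows library pool and time of day here, stays a candidate explanation beside a rhythm. The GC correction left 8691 called genes, the GC correlation as a term 6361 and the pool group as a term 12019. The pool group parts CT0, CT4 and CT8 from the other hours, so it cannot take up a shift between CT0 and CT4 or CT8. The share of reads of the non-coding RN7SL2 moved with the GC correlation. Its medians in entrained SC islets were 2.2% at CT4, 2.5% at CT8 and 6.4% to 9.1% at the other hours. In the 3 libraries it was 8.3%, 10.8% and 2.4%, following their GC sign. RNA or library quality is therefore not separated from time of day.

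INS had the swing of 3.55 in entrained SC islets. With the GC correlation of each library as a term it was 0.56, and turned against its peak. A library-wide shift may account for the swing. But the term comes from the same libraries and nearly follows the time of day, so it would take up a true rhythm of that phase too. The smaller swing therefore does not tell these apart. In mock islets the INS swing along the entrained phase was 82.4% of that of entrained islets over CT0 to CT20. But the mock fit of INS did not pass the test. The median GC correlation was also below 0 at CT4 and CT8 in both arms. The ratio therefore does not decide whether entrainment adds to the INS swing. With the correction by bins of GC content INS kept a swing of 1.84, so a part beyond the shared trend of genes of its GC content is open. Pool was not separated from time of day, since the fit with the library pool as a term was not run. The 2 are partly crossed. Within pool 1 the GC correlation of primary libraries ran from -0.208 to 0.603 at CT0 and from -0.817 to -0.795 at CT4. Pool alone therefore does not set it there.

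The core clock genes are the third pattern: 5 of 20 differed in rhythm between arms at an unadjusted p under 0.05 after either GC correction, against 1 without. Their median F lay at percentile 98.31 of random lists with the GC correlation as a term (99.5 with the GC correction, 85.99 without), but since the pattern is absent without a correction, the bound set beforehand decides nothing here, and a product of the correction or a rest of the shift stays open. With the correction 10 of 20 clock genes had the larger swing in entrained islets and without it 13, so a gain of rhythm with entrainment is neither shown nor excluded. Of the 10 splits of the 6 series, 1, the real split, gave as many clock genes with the GC correction (real 5, highest other 3) and 1 with the GC correlation as a term (real 5, highest other 4), and 10 splits are too few for a share under 0.05. A difference of phase or of a few genes such as NR1D2, PER2 and NR1D1 stays open as a hypothesis, untested on other data.

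The other comparisons of 3 with 3 series also have 10 splits, too few for a share under 0.05. For genes at an unadjusted p under 0.05 between entrained and mock islets, 5 splits gave as many (real 769, highest other 2871), a count several times the real one, which points to a structure of the samples. With blocks taken as pairs in column order, the other splits that part all 3 pairs gave 79, 46 and 42. That pairing comes from the data and not from the design. For gene lists 1 of the 10 splits gave as many, the real one (real 16, highest other 13). For day 3 against day 1, 4 splits gave as many (real 1220, highest other 2329), and with the column block as a term 348 genes were called in the real split and 11 at most in the others that part all 3 pairs. For clock genes with a difference in rhythm in the uncorrected fit, 4 splits gave as many (real 1, highest other 2), which does not speak to the pattern after correction. For all genes with a difference in rhythm between arms, 6 splits gave as many (real 212, highest other 1166), again several times the real count, which points to a structure of the samples.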

How the results depend on the processing

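For the time courses, limma on normalized values, the constants added to them, TMM scaling, edgeR with TMM on recovered reads, the pool group, both GC corrections, the fits without shallow libraries or those of the other GC sign and the fits of 36 libraries were chosen after the data were seen, and the other settings named here before.

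Of 8547 alternative values over 1175 results, 183 are counts of genes or lists, of which 134 were classed as the same and 49 as moved. The class of the same is broad and does not mean an unchanged value. In entrained SC islets it holds the rhythm count of 12760 against 8691 with the GC correction and against 15538 with DESeq2. It also holds counts of 0 that stayed at 0. For single genes 7153 were classed as the same, 758 as moved, 238 as weaker, 170 as stronger and 45 as turned around. These too are classes, so a gene classed as the same can have another swing or size. Where counts moved, the cause was not tested.

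GC correction: the rhythm count over CT0 to CT20 in entrained SC islets went from 3018 to 376, in primary islets from 7906 to 1184, and the difference between primary and SC islets from 6468 to 2041. Swings that turned against the uncorrected peak in entrained SC islets were ARNTL2 -0.025, CRY2 -0.0091, DBP -0.47, TEF -0.12, GCG -0.055, UCN3 -0.054, IAPP -0.030 and JUND -0.62. In primary islets they were CRY2 -0.041, DBP -0.46, TEF -0.18 and MAFA -1.56, and in the difference between systems DBP -0.019, GCG -0.052 and IAPP -0.017.

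GC correlation as a term: the count in entrained SC islets went from 12760 to 6361, over CT0 to CT20 from 3018 to 164, in mock SC islets from 466 to 986, in primary islets from 7906 to 0 and for the difference between systems from 6468 to 1501. In entrained SC islets ARNTL2 -0.33, CLOCK -0.42, PER1 -0.80, CRY2 -0.26, NR1D2 -0.030, RORA -0.34, DBP -0.28, TEF -0.24, BHLHE40 -0.21, INS -0.23, SST -0.33, UCN3 -0.28 and IAPP -0.094 turned. Over CT0 to CT20 so did PER1 -0.42, NR1D2 -0.097, INS -0.10 and SST -0.18. In primary islets CLOCK -0.19, PER1 -0.38, CRY2 -0.22, NR1D1 -0.81, RORA -0.43, DBP -0.68, TEF -0.72, BHLHE40 -0.24, BHLHE41 -0.13, INS -0.50, MAFA -0.13 and UCN3 -0.81 turned, and in the difference between systems INS -0.12.

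Other settings for rhythm: with at least 1.5-fold from trough to peak 6898 genes remained in entrained SC islets. Over CT0 to CT20 the count was 604 without a filter, 171 with edgeR and TMM, 172 with edgeR and RLE, 0 with the pool group as a term, 6609 without the libraries of the other GC sign and 0 to 845 with 1 series left out. In mock SC islets it was 91 with 1 added, 212 without a filter, 1 with edgeR and TMM, 124 with edgeR and RLE, 0 with the pool group, 2597 without libraries under 1500000 reads, 5030 without those of the other GC sign and 0 to 1062 with 1 series left out. In primary islets the pool group left 1 gene, while it left 12019 in entrained SC islets and 6755 for the difference between systems. The difference between systems had 3161 to 5844 genes with 1 SC series left out, among them 4308 without block 4.

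Entrained against mock: the count of 0 became 2 after TMM scaling, 117 with DESeq2, 0 to 2 with 1 series left out, 195 with 36 libraries and the series as a random effect, and 188 with the GC correlation added to that fit. The 16 lists became 0 with an estimated correlation and 0 with fry for a shared direction. The mixed test of fry passed for glucocorticoid targets, immediate early genes and glucose-responsive ChREBP targets. No paired fit of the arms was run. The titles number both arms 1 to 3, but the columns carry no replicate numbers, so pairs could be set only by column order or values. The count of 0, its splits and its lists therefore rest on fits without pairs and could differ with pairs. Taken in column order, mock and entrained blocks deviate together (correlations of 0.706, 0.552 and 0.773, all other combinations below 0), a hint from the data and not from the design. Deviations are taken from the mean of an arm's 3 series. A match above 0 therefore presses the other combinations below 0, and their sign adds little. For day 3 against day 1 the count of 0 became 1 with edgeR and TMM, 1 with edgeR and RLE, 35 with DESeq2 and 348 with the column block as a term.

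Cell types with a minimum of 5 CPM in place of 20: DE against hPSC went from 863 to 1408, PP1 against DE from 872 to 1395, PP2 against PP1 from 347 to 599, SCbeta against EN from 849 to 1370, SCbeta against PH from 139 to 220, SCbeta against Beta from 1036 to 1725 and Alpha against Beta from 446 to 709. With 5 CPM added SCbeta against PH had 82. These rises follow by construction from the lower minimum.

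The library pool as a further term was planned and not run for the rhythms of SC and primary islets, their difference and the lists. SC libraries of CT4, CT16 and the same hours of later days lie in 2 pools, and columns without replicate numbers were assigned to none, although 2 files that equal a column point to replicate 1 for entrained block 2 and replicate 3 for block 4. In primary islets a cosine and a sine are not both estimable beside the pools. Depth limits the mock primary islets to 1 time, and a difference in rhythm of 1 log2 between arms was recovered for 4 of 200 simulated genes.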

Other observations

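The tests proposed here were chosen after the results were seen, and none was run.

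Clock genes of entrained SC islets, a part of those that passed, are listed here by their peak after the GC correction. NR1D1 peaks at 23.3 h, CIART at 1.25 h, PER3 at 2.74 h, NR1D2 at 3.38 h, DBP at 5.25 h, PER2 at 7.12 h, CRY1 at 13.03 h, ARNTL at 16.4 h and NPAS2 at 18.7 h. Over CT0 to CT20 alone the corrected peaks of NR1D1, CIART and PER2 lay later than these. With the GC correlation of each library as a term, NR1D2 turned against its uncorrected peak, and ARNTL, NPAS2 and DBP did not pass (adjusted p = 0.201, 0.163 and 0.146, limma), so this order rests on the form of the correction. Peaks in labelled hours depend on the hour taken as 0.

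Some genes, picked for their values on day 1, stand higher on the first entrained day than in mock islets and on day 3. Day 2 was not compared. In CPM for mock, day 1 and day 3, G0S2 is at 4.79, 14.9 and 4.76, SGK1 at 2.41, 9.19 and 4.99, COL1A1 at 5.32, 12.04 and 5.71, RGS9 at 21.5, 33.9 and 23.6 and ECEL1 at 0.816, 6.86 and 2.49, while ID1 goes the other way, at 25.4, 12.4 and 31.9. Both comparisons share the day 1 libraries, so the opposite signs arise by construction. A response to handling that fades is 1 hypothesis. Mock libraries of days 2 and 3 would test it.

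The hPSC library holds GCG at 85.5 CPM, TTR at 59.6 CPM and CHGA at 49.4 CPM. Sharing of reads between libraries sequenced together is 1 hypothesis, and splice junction reads of these genes with their barcodes would test it.

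Randomizing times of day over library pools, or sequencing again from stored RNA in a new pool order, would separate pool from time. If the 3 libraries of the other GC sign keep their sign in new libraries, the cause lies in the RNA and not in the pool.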
